A study of Mus musculus with 9 samples.

How the data were processed

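The data are 9 RNA-seq libraries of mouse embryonic forebrain, 3 for each of sh-NT, sh-Gpc4 and sh-Gpc2. Per the labels' protocols, RNA was isolated with a kit for very small samples and libraries were made with a low-input kit that amplifies cDNA. The deposited table holds raw read counts per gene, 1 column per library. Per the submitters' processing notes, the authors counted with featureCounts of the Subread package and named the builds GRCm38 and mm10. The aligner, the annotation release, all versions and whether strand was used are not given in the sources used here, so reads of overlapping and antisense genes cannot be separated. PCR duplicates cannot be recognised in a count table.

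The table has 78275 gene IDs and no row without a gene. Symbols came from a table of GENCODE M21 IDs, which matched 51486 IDs (65.8%), holding 96.8% to 97.0% of the reads of each library. The other IDs are of a later release than M21 although GRCm38 is named, and are printed as IDs. The 37 mitochondrial genes had 0 reads in every library, so mitochondrial content could not be used as a check of cell quality. Total counts ran from 48045603 to 66538437 reads. Counting error is small beside the spread between libraries for abundant genes but not for genes below 1 CPM, such as Cdh1 and Epas1. Each edgeR p-value rests on the spread within groups over all 9 libraries, so it also carries the spread of the group not compared. No label says whether the libraries of a group came from separate litters. A column's name gives its group, but its number does not match the replicate numbers of the sample titles, so no column was tied to a titled replicate. Counts of each pair of libraries of a group differed by far more than sampling noise (chi-square per degree of freedom of 7.65 to 81.7), and none was treated as a duplicate.

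Tests ran in R 4.3.3 on the counts as deposited. The edgeR 4.0.16 quasi-likelihood test was fitted to all 9 libraries with 1 coefficient per group, TMM normalization and the default filter on low counts, which kept 27773 genes. The 3 contrasts were sh-Gpc4 against sh-NT, sh-Gpc2 against sh-NT and sh-Gpc4 against sh-Gpc2. P-values were adjusted by Benjamini-Hochberg over all tested genes of a contrast, with a threshold of 0.05. CPM values are TMM-scaled. SE values are the log2 fold change divided by the square root of the test's F, and intervals use the test's degrees of freedom (median 9.50). The 30 gene lists were fixed before the data were examined. Camera of limma 3.58.1, with a preset correlation between genes of 0.01, tested the 28 lists with at least 5 tested genes, on log2 CPM with a prior count of 2, and adjusted p over the 28. The choroid plexus list had 4 tested genes and the mitochondrial list 0, so neither was tested. Of list genes, 5 of 30 for radial glia, 4 of 20 for intermediate progenitors, 6 of 24 for newborn neurons, 3 of 16 for upper-layer and 1 of 18 for deep-layer neurons are also in another list. So are 2 of 12 for mural cells, 2 of 10 for oligodendrocyte precursors, 3 of 13 for Cajal-Retzius cells, 4 of 15 for hippocampal cells and 1 of 11 for choroid plexus. None is for microglia, GABAergic, endothelial, erythroid or meningeal cells. Notch shares 8 of 24 genes, axon guidance 9 of 46, FGF/ERK targets 6 of 22 and dissociation stress 5 of 22. Camera was repeated with a correlation estimated per list, and fry tested whether each list moved one way. Members of a list were also adjusted over that list alone, with no correction across lists or comparisons.

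Genes named in the text follow a rule fixed before the data were examined. It takes Gpc4 and Gpc2, then for each contrast up to 12 genes per direction past the threshold, filled up to 6 with the smallest p where fewer pass. It leaves out predicted genes (names of Gm with a number, Rik or numbered ps suffixes) and 6 sex-linked genes, and adds up to 4 members of each described list. Since IDs without a symbol filled some places, the next genes with a symbol were added after the values were seen, so that 6 per direction have a name. Single values of 4 list members are not reported here; they stay in the list tests.

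Alternatives planned before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma voom with sample weights, no filter, a filter of more than 5 CPM in at least 3 libraries, fits of only the 2 groups compared, and leaving out each library. A replicate block by column number, removal of the GC trend, a microglia covariate, and leaving out 2 libraries together were added after seeing the data. The GC trend was a smooth spline with 6 degrees of freedom of each library's log2 CPM on the GC content of the longest GENCODE M21 transcript, for the 22126 tested genes with a match; the other 5647 have no GC value and were left out of that fit. Principal components used genes with a mean log2 CPM above 3.

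Before use, the edgeR and camera steps were tested on simulated counts of the 27773 genes with 200 changed genes per contrast. For sh-Gpc4 against sh-NT 29 of 100 genes changed by 2-fold and 75 of 100 changed by 4-fold were recovered, with 6 calls among unchanged genes. For sh-Gpc2 against sh-NT these numbers were 30, 83 and 8, and for sh-Gpc4 against sh-Gpc2 35, 81 and 5. A list shifted in the simulated counts had adjusted p of 1.99e-11, 9.16e-19 and 1.13e-17 in camera with the preset correlation and 0.0892, 0.00125 and 0.00278 with an estimated one, so the latter missed it in sh-Gpc4 against sh-NT. Each contrast was simulated a single time, so differences between contrasts in these numbers may lie with the draw. Simulated genes vary independently of one another. In the sort, cells without the hairpin or with little knockdown cannot be told from others by these counts.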

Results

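RNA was sequenced from mCherry-positive cells of the mouse embryonic cerebral cortex, sorted by flow cytometry at E16.5. The cells had been transfected by in utero electroporation 48 h earlier, at E14.5, with a plasmid that expresses mCherry and a microRNA-embedded short hairpin RNA (shRNA). The hairpin was directed against Gpc4 (sh-Gpc4), against Gpc2 (sh-Gpc2), or was a scrambled control (sh-NT), with 3 libraries in each group. Gpc4 and Gpc2 encode glypicans, heparan sulfate proteoglycans tethered to the cell surface by a lipid anchor. The series asks how loss of each glypican affects cortical development. The labels describe the sorted cells as progenitors and neurons of the cortex. The columns of the count table carry the numbers 1, 2 and 4 for sh-NT and sh-Gpc2 and 1, 3 and 4 for sh-Gpc4, and libraries are named by these numbers here. Total counts were 62004280, 58950935 and 59478504 reads for sh-NT libraries 1, 2 and 4. They were 50333500, 64922652 and 66538437 reads for sh-Gpc4 libraries 1, 3 and 4, and 56195268, 64186976 and 48045603 reads for sh-Gpc2 libraries 1, 2 and 4. Nothing in the labels says whether the libraries of a group came from separate animals or litters, so the p-values measure only the spread between these samples.

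Transcripts of the targeted genes were lower on average in the matching group, with a spread that left neither difference past the threshold. Gpc4 (ENSMUSG00000031119, GRCm38 chromosome X, 52053021 to 52165252, minus strand, protein-coding) was at 176 ± 11.9 CPM (read counts scaled to library size; mean ± SD, n = 3) in sh-NT and at 122 ± 19.8 CPM in sh-Gpc4. The sh-NT libraries held 165, 188 and 175 CPM and the sh-Gpc4 libraries 137, 99.9 and 129 CPM, so the groups did not overlap. The same held for 24% of all genes tested in this comparison, and sh-Gpc2 library 4, without this hairpin, held 116 CPM. The log2 fold change of Gpc4 in sh-Gpc4 was -0.53 (SE 0.21, 95% interval -0.997 to -0.0538), a ratio of 0.695, with an adjusted p of 0.488 in edgeR's quasi-likelihood test. A two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Gpc2 (ENSMUSG00000029510, GRCm38 chromosome 5, 138273655 to 138280005, minus strand, protein-coding) was at 189 ± 24.7 CPM in sh-NT and at 131 ± 45.6 CPM in sh-Gpc2. The sh-NT libraries held 200, 207 and 161 CPM and the sh-Gpc2 libraries 167, 145 and 79.6 CPM. The log2 fold change of Gpc2 in sh-Gpc2 was -0.54 (SE 0.33, 95% interval -1.28 to 0.21), a ratio of 0.690, with an adjusted p of 0.968 in edgeR and an exact permutation p of 0.2. Without sh-Gpc2 library 4 it was -0.28.

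Each gene was also measured under the hairpin against the other. Gpc2 was at 112 ± 50.7 CPM in sh-Gpc4, with 168, 70.3 and 96.6 CPM in libraries 1, 3 and 4, a log2 fold change of -0.76 (SE 0.33) against sh-NT with an adjusted p of 0.488 in edgeR. It was -1.18 without sh-Gpc4 library 1 and -0.51 without library 3. Gpc4 was at 159 ± 51.8 CPM in sh-Gpc2, with 145, 216 and 116 CPM in libraries 1, 2 and 4, a log2 fold change of -0.15 (SE 0.21, 95% interval -0.62 to 0.32) that turned to 0.04 without sh-Gpc2 library 4 and was -0.43 without library 2. Directly between the 2 knockdown groups, the log2 fold change of sh-Gpc4 over sh-Gpc2 was -0.38 (95% interval -0.85 to 0.09) for Gpc4 and -0.23 (95% interval -0.97 to 0.52) for Gpc2. Exact permutation p was 0.4 and 0.8. The annotation release behind the deposited gene IDs is not given in the sources used here, and the coordinates are those of GENCODE M21.

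**Figure D1:**
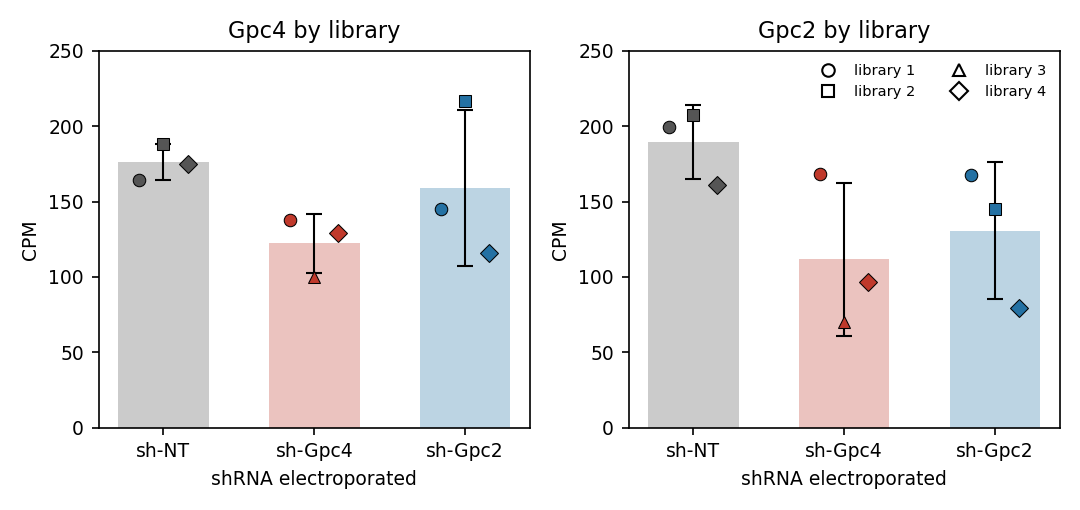
CPM of Gpc4 (left) and Gpc2 (right) in each library, by electroporated hairpin; bars are means of 3 libraries, error bars are SD and marker shapes give the library number. The sh-Gpc4 libraries lie at 99.9 to 137 CPM for Gpc4, below all sh-NT libraries, while Gpc2 in sh-Gpc2 library 1 (167 CPM) lies within the sh-NT range.

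In sh-Gpc4 against sh-NT, the genes with the smallest p lay in both directions. Lower genes included Cdh1 (E-cadherin, a cell adhesion molecule), Slc16a11 (a member of the monocarboxylate transporter family), S1pr4 (a sphingosine 1-phosphate receptor), Epas1 (the hypoxia-inducible factor HIF-2 alpha), Plagl2 (a zinc finger transcription factor) and Tmem56. Tmem56, Ddx4, Rmst and Msmo1 were added after the values were seen. Plagl2 was at 22.9 ± 0.625 CPM in sh-NT and 15.9 ± 1.14 CPM in sh-Gpc4 (log2 fold change -0.53, SE 0.11, n = 3 each), and Tmem56 at 15.0 ± 0.863 and 9.22 ± 0.560 CPM (-0.71, SE 0.15). Cdh1 (log2 fold change -2.06, SE 0.35), Slc16a11 (-1.57, SE 0.28), S1pr4 (-1.86, SE 0.37) and Epas1 (-2.49, SE 0.50) were at less than 1 CPM in sh-NT, between 0.302 and 0.710 CPM. A lower gene without a symbol, ENSMUSG00000122360, went from 5.77 ± 1.02 to 1.59 ± 0.673 CPM. Higher values were found for Siah2 (an E3 ubiquitin ligase; 1.94 ± 0.136 against 3.4 ± 0.282 CPM, log2 fold change 0.81, SE 0.17), Slc15a2 (a peptide transporter; 32.8 ± 5.74 against 50.2 ± 2.93 CPM, 0.62, SE 0.13) and Msmo1 (an enzyme of sterol synthesis; 154 ± 9.61 against 198 ± 10.9 CPM, 0.36, SE 0.08). Higher by p were also Snord47 (a small nucleolar RNA whose reads may overlap a host gene; log2 fold change 0.55, SE 0.12), Ddx4 (0.82, SE 0.19), Rmst (a long noncoding RNA; 1.55, SE 0.36) and 3 IDs without a symbol, ENSMUSG00000119320 (0.81, SE 0.15), ENSMUSG00002076960 (0.92, SE 0.19) and ENSMUSG00000139821 (1.32, SE 0.28). None of them passed: of 27773 genes tested, 0 had an adjusted p under 0.05 in edgeR, and the smallest was 0.488. At an unadjusted p under 0.05 there were 2657 genes, 988 higher and 1669 lower. The libraries of the groups did not overlap for 6669 genes, 24% of those tested, where chance gives 10%.

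DESeq2's Wald test on the same counts called 45 genes in sh-Gpc4 against sh-NT, 13 higher and 32 lower. Limma voom with sample weights called 0, but its smallest adjusted p was 0.0531, close to the threshold. In voom 9011 genes had an unadjusted p under 0.05. The genes named above that DESeq2 called were Plagl2, Tmem56, Cdh1, Epas1, Siah2, Slc15a2, Snord47, Rmst, ENSMUSG00000122360, ENSMUSG00000119320 and ENSMUSG00002076960. Others among its calls, chosen after their values were seen, include genes at higher levels. Zfand5 was at 157 ± 14.4 CPM in sh-NT and 93.4 ± 6.94 CPM in sh-Gpc4, Plekhf2 at 133 ± 22.1 and 64.4 ± 10.9 CPM, and Mvb12b at 76.9 ± 6.09 and 39.1 ± 7.2 CPM. Frs2, an adaptor of fibroblast growth factor receptors, was at 62.6 ± 2.12 and 43.7 ± 5.08 CPM. Flrt2, a membrane protein of axon guidance and neuron migration, was at 43.6 ± 2.04 and 28.7 ± 0.724 CPM. Itgav, the integrin alpha V subunit, was at 32.9 ± 1.35 and 25.3 ± 0.921 CPM, and Nog, the secreted BMP antagonist noggin, at 2.20 ± 0.492 and 0.711 ± 0.188 CPM. For the called genes checked under the other 18 alternatives, the adjusted p ran from 0.0531 to 0.963.

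Lists of heparan sulfate core proteins, Notch and Hedgehog pathways, axon guidance, FGF/ERK targets, intermediate progenitors and S phase lay lower in sh-Gpc4 than in sh-NT, while Wnt and BMP target lists did not pass. All 14 measured members of the list of glypicans and other heparan sulfate core proteins had negative log2 fold changes (median -0.47). Among them were Hspg2 (perlecan, 6.59 ± 0.575 against 3.25 ± 1.21 CPM) and Sdc3 (syndecan 3, 79.4 ± 5.87 against 50.3 ± 15.8 CPM). Gpc4 and Gpc2, the targets of the hairpins, are members of this list too, and it was not tested without them. In the Notch pathway list 21 of 23 members were negative (median -0.36), with Dtx1 (-1.11, SE 0.33) and the ligands Jag1 (-0.45, SE 0.13), Dll4 (-1.37, SE 0.45) and Dll1 (-0.85, SE 0.34). In the list of axon guidance and migration receptors and ligands 31 of 44 were negative (median -0.19), with Flrt2 (-0.60, SE 0.13), Sema6d (-0.41, SE 0.13), Efnb1 (-1.24, SE 0.40) and Slit2 (-0.43, SE 0.16). Camera with the preset correlation gave adjusted p of 0.00165, 0.00102 and 0.00381 for these lists, and in each the mean of all 3 sh-Gpc4 libraries lay below every sh-NT library. Adjusted p with an estimated correlation was 0.721 for each. Intermediate progenitor genes were negative for 15 of 20 (median -0.20, camera adjusted p = 0.0173, 0.721 with an estimated correlation), with Dll3 (-0.88, SE 0.37) and Neurog1 (a proneural factor; -1.58, SE 0.69). Hedgehog pathway genes were negative for 11 of 12 (median -0.36, 0.0173, 0.721 with an estimated correlation), with Gli2 (-0.95, SE 0.34) and Gli1 (-1.05, SE 0.40). FGF/ERK targets were negative for 16 of 22 (median -0.25, 0.0388, 0.721 with an estimated correlation), where Egr1 was at -0.87 (SE 0.32) and Dusp6, an ERK phosphatase, at 0.55 (SE 0.20). S phase genes were negative for 33 of 43 (median -0.10, 0.0388, 0.834 with an estimated correlation), with E2f8 (-0.72, SE 0.33) and Uhrf1 (-0.73, SE 0.36). With the GC trend removed the preset adjusted p was 0.665 for intermediate progenitors, 0.116 for Hedgehog and 0.220 for FGF/ERK targets, so these calls ended. With the microglia list as a covariate it was 0.852 for S phase, 0.142 for FGF/ERK targets and 0.0720 for Hedgehog, and S phase passed in only 4 of the 9 fits with a library left out.

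Markers of other cell types and of cell state also lay apart in sh-Gpc4. Microglia and macrophage markers were positive for 19 of 20 (median 0.44, camera adjusted p = 0.0173, 0.834 with an estimated correlation), with P2ry12 at 23.9 ± 4.34 CPM in sh-NT and 53.9 ± 4.76 CPM in sh-Gpc4 and C1qb between 111 and 333 CPM over the 9 libraries. Relative to its overall mean, the microglia list was at 0.62 log2 units in sh-Gpc4 library 4, above every sh-NT library. But sh-NT library 4 (0.21) lay above sh-Gpc4 libraries 1 (0.06) and 3 (0.17). The interferon response list was positive for 15 of 25 (median 0.26, 0.0305, 0.834 with an estimated correlation), with Ifit3 (1.27, SE 0.39), Rsad2 (1.36, SE 0.45), Ifit1 (1.01, SE 0.34) and Ifit2 (0.58, SE 0.18), although no sh-Gpc4 library's list mean exceeded that of sh-NT library 2. Oligodendrocyte precursor markers were negative for 5 of 7 (median -1.02, 0.0173, 0.721 with an estimated correlation). Adjusted over the list alone, Olig2 (-1.87, SE 0.53), Pdgfra (-1.02, SE 0.30) and Cspg4 (-1.29, SE 0.40) passed at an adjusted p of 0.0218 each in edgeR. This adjustment makes no correction across the lists or comparisons. Olig2 was scarce, at 0.210 to 3.13 CPM over the 9 libraries, with 0.966 CPM in sh-NT library 1 and 0.766 CPM in sh-Gpc4 library 4. Mural cell markers were negative for 9 of 11 (median -0.34, 0.0173, 0.721 with an estimated correlation), with Notch3 (-1.09, SE 0.44) and Pdgfrb (-1.11, SE 0.46). Markers of GABAergic interneurons and ventral progenitors were negative for 14 of 18 (median -0.51, 0.0386, 0.721 with an estimated correlation), with Dlx2 (-4.06, SE 1.28). That list stood 1.29 log2 units above its mean in sh-NT library 1 and below its mean in the other sh-NT libraries. The oligodendrocyte precursor list was at -1.32 in sh-Gpc4 library 3 against -0.20 and -0.29 in libraries 1 and 4, and its adjusted p was 0.0933 without the 2 libraries that lie apart. With the GC trend removed the calls of the mural (0.116) and GABAergic (0.129) lists ended. Limma voom ended those of the mural (camera adjusted p 0.0820), oligodendrocyte precursor (0.0820) and GABAergic (0.0701) lists, and kept microglia (2.3e-06) and interferon response (0.00460). In all, 12 of 28 lists passed, 2 higher and 10 lower; 5 passed with genes restricted to over 5 CPM and 7 without sh-NT library 1. Fry, which tests for a shift in one direction, gave none (smallest adjusted p 0.469). Over all genes tested no member of any list passed in edgeR, while DESeq2 called Nog and Flrt2 (adjusted p of 0.0454 and 0.0440), and adjusted over the list alone the members that passed were Olig2, Pdgfra, Cspg4 and, among BMP/TGF-beta targets, Nog (0.0404 in edgeR).

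Lists of neuronal layers did not pass in sh-Gpc4 against sh-NT. Upper-layer neuron genes were positive for 8 and negative for 8 (median 0.01, camera adjusted p = 0.940). Newborn and migrating excitatory neuron genes were positive for 11 and negative for 13 (median -0.01, 0.759), with Plxna2 at -0.43 (SE 0.16) and Stmn2 at 0.52 (SE 0.21). Deep-layer genes had a median of 0.09, a mean of -0.08 and an upward camera direction (0.874), with Wnt7b at -1.45 (SE 0.47; 155 ± 21.3 against 56.6 ± 23.7 CPM). Radial glia genes were negative for 21 of 30 (median -0.07, 0.0801), with Nr2e1 at -0.65 (SE 0.21) and Notch1 at -0.68 (SE 0.30), and G2 and M phase genes had a median of 0.01 (0.559). The G2 and M phase list passed downward without the 2 libraries that lie apart (0.00940), with the microglia covariate (0.0406) and with limma voom (0.00460).

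**Figure D2:**
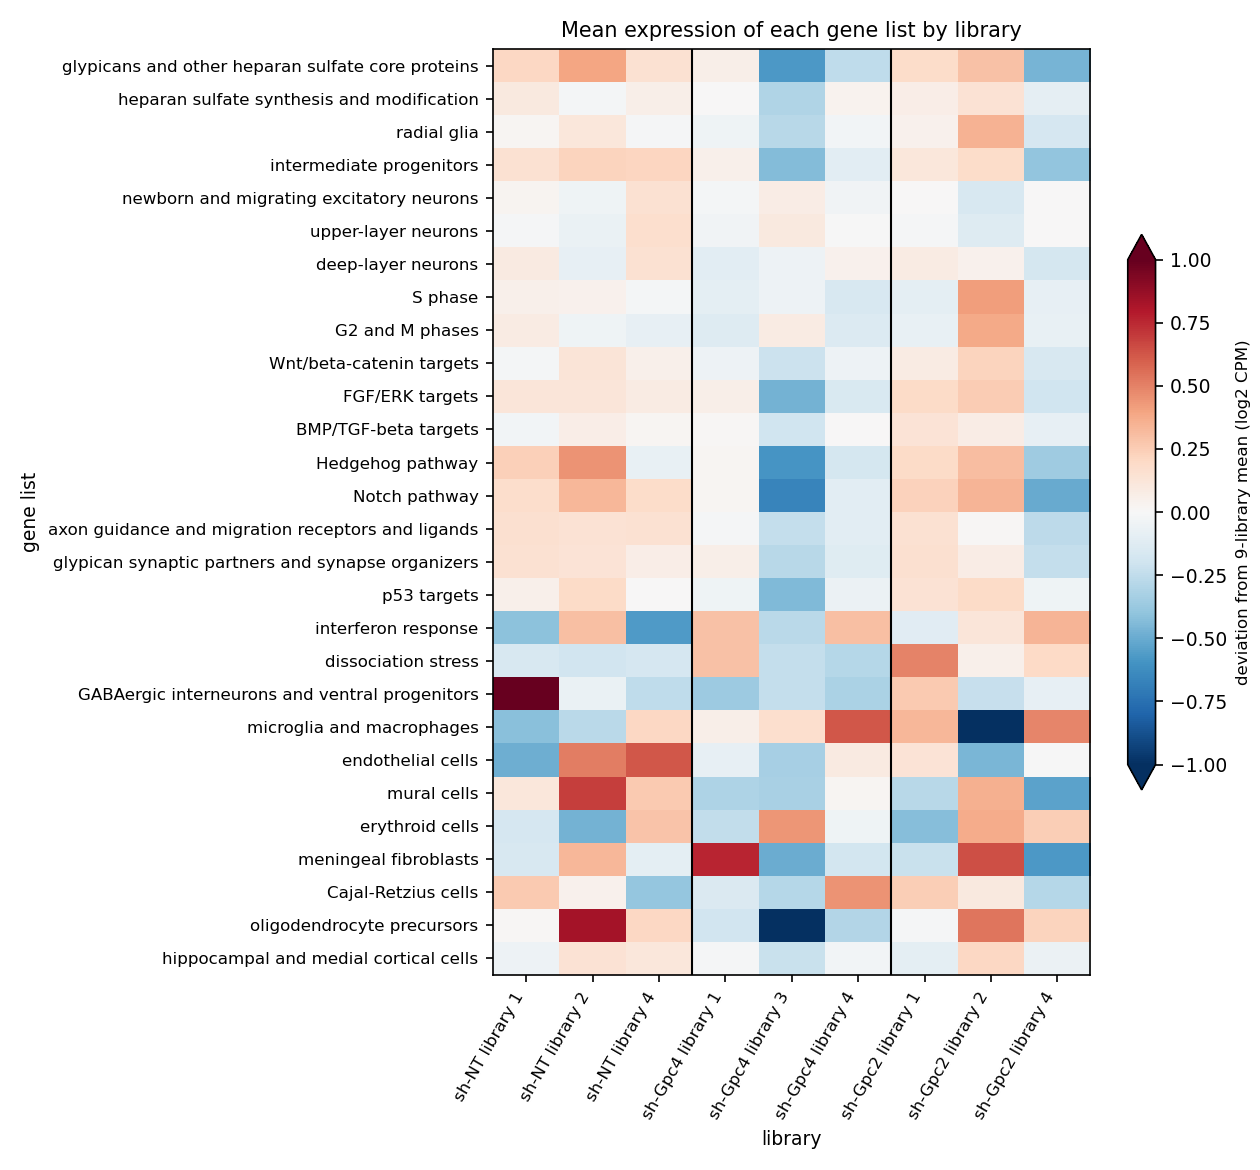
Mean log2 CPM of each tested gene list in each library, as a deviation from the mean of the 9 libraries (colour, log2 units; the scale ends at 1 in either direction); vertical lines part the groups. Notch pathway genes are lowest in sh-Gpc4 library 3 (-0.66) and sh-Gpc2 library 4 (-0.51), and cell cycle lists are highest in sh-Gpc2 library 2 (0.42 for S phase).

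In sh-Gpc2 against sh-NT, the dissociation stress list lay higher. These genes, which respond to tissue handling and heat shock, were positive for 19 of 22 (median 0.35, camera adjusted p = 1.9e-06, 0.761 with an estimated correlation), and all 3 sh-Gpc2 libraries had a list mean above every sh-NT library. The heat shock gene Hspa1a was at 11.6 ± 1.90 CPM in sh-NT and 37.5 ± 12.4 CPM in sh-Gpc2 (log2 fold change 1.69, SE 0.40) and its near-identical copy Hspa1b at 0.570 ± 0.170 and 1.87 ± 0.789 CPM (1.71, SE 0.41), so the reads of this pair cannot be told apart with certainty. Fos was at 329 ± 13.3 and 483 ± 60.9 CPM (0.56, SE 0.16), and Hspb1 had a log2 fold change of 1.72 (SE 0.54). Egr1 (-0.55, SE 0.32) and Ier2 (-0.02, SE 0.23), also of this list, were negative. Adjusted over the list alone, Hspa1a and Hspa1b passed (0.0238 each in edgeR). Cdkn1a, the cell cycle inhibitor p21, was at 25.0 ± 0.627 and 37.2 ± 6.15 CPM (0.57, SE 0.14) and was the only one of the p53 targets to pass over the list alone (0.0498), and Id1, a BMP target, had a log2 fold change of 0.47 (SE 0.12; 0.0489 over its list alone).

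Single genes gave no call in sh-Gpc2. The higher genes with the smallest p were Gpr50 (log2 fold change 1.81, SE 0.37), Pou4f3 (1.39, SE 0.30), Cbln4 (1.6, SE 0.37) and 3 IDs without a symbol, all at or below 1.23 CPM, followed by Hspa1a, Hspa1b and Cdkn1a, which were added after the values were seen. The lower genes were Zkscan1 (142 ± 5.88 against 109 ± 4.77 CPM, -0.39, SE 0.08), Slc16a11 (-1.01, SE 0.27), Mlh3 (a DNA mismatch repair gene; -0.36, SE 0.10), Frs2 (62.6 ± 2.12 against 46.8 ± 5.35 CPM, -0.42, SE 0.12), Plagl2 (-0.39, SE 0.11), Zfp397 (-0.31, SE 0.09) and 2 IDs without a symbol. Of 27773 genes 0 passed in edgeR (smallest adjusted p 0.968), 0 in DESeq2 and 0 in limma voom. At an unadjusted p under 0.05 edgeR had 712 genes, 449 higher and 263 lower, where 1389 are expected by chance. Groups did not overlap for 2138 genes, 7.70% against the 10% of chance.

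Other lists that passed camera in sh-Gpc2 against sh-NT were higher for the interferon response and for G2 and M phases, and lower for axon guidance, mural cells, intermediate progenitors, Notch and heparan sulfate core proteins. The axon guidance list was negative for 37 of 44 (median -0.16, adjusted p = 0.000233, 0.860 with an estimated correlation), with Flrt2 at -0.44 (SE 0.13) and Plxna2 at -0.32 (SE 0.16). Interferon response genes were positive for 24 of 25 (median 0.35, 0.000272, 0.927 with an estimated correlation), with Rsad2 at 0.88 (SE 0.45). The mean of this list was 0.30 in sh-NT library 2, above sh-Gpc2 libraries 1 (-0.11) and 2 (0.12), and -0.41 and -0.57 in sh-NT libraries 1 and 4. G2 and M phase genes were positive for 45 of 53 (median 0.14, 0.00275, 0.927 with an estimated correlation), with Ube2c at 0.28 (SE 0.16). Only 1 sh-Gpc2 library, library 2, had a list mean above every sh-NT library. Libraries 1 and 4 (-0.07 and -0.08) lay below the sh-NT group mean (-0.01), and the direction held in 8 of the 9 fits with a library left out. Mural cell markers were negative for 9 of 11 (median -0.57, 0.00168, 0.761 with an estimated correlation), with Kcnj8 at -1.06 (SE 0.37). Intermediate progenitor genes were negative for 17 of 20 (median -0.10, 0.0209, 0.927 with an estimated correlation), with Nhlh1 at -0.46 (SE 0.21). Notch pathway genes were negative for 18 of 23 (median -0.19, 0.0209, 0.927 with an estimated correlation), while Hey1, a Notch target, was at 0.37 (SE 0.15). Heparan sulfate core protein genes, Gpc4 and the target Gpc2 among them, were negative for 11 of 14 (median -0.15, 0.0351, 0.927 with an estimated correlation), with Gpc1 at -0.22 (SE 0.17). The Notch and heparan sulfate lists were low in sh-Gpc2 library 4 alone (-0.51 and -0.47, against 0.19 to 0.34 in libraries 1 and 2). Without the 2 libraries that lie apart their adjusted p was 0.690 each, with Notch then upward, and it was 0.348 for intermediate progenitors. With the GC trend removed it was 0.138 for Notch and 0.309 for intermediate progenitors. In all 8 of 28 lists passed, 3 higher and 5 lower, and none held with an estimated correlation or with fry (smallest 0.714). Microglial markers had a median of 0.28 (0.545) with a list mean 1.20 log2 units below its overall mean in sh-Gpc2 library 2.

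Directly between the knockdowns, radial glia and cell cycle lists were lower in sh-Gpc4 than in sh-Gpc2. S phase genes were negative for 41 of 43 (median -0.18, camera adjusted p = 3.93e-06), G2 and M phase genes for 49 of 53 (median -0.14, 7.73e-05) and radial glia genes for 29 of 30 (median -0.14, 0.000221). Examples were Mcm5 (111 ± 11.1 CPM in sh-Gpc4 and 143 ± 47.2 CPM in sh-Gpc2), Aurkb (92.0 ± 2.08 and 117 ± 33.8 CPM), Sox2 (17.6 ± 0.756 and 20.9 ± 2.25 CPM) and Sox9 (240 ± 65.8 and 336 ± 119 CPM). With an estimated correlation the adjusted p was 0.718 for each of these lists. Their means were high in sh-Gpc2 library 2 alone (0.42 for S phase, 0.38 for G2 and M phases and 0.35 for radial glia, against -0.17 to 0.04 in sh-Gpc2 libraries 1 and 4). For the cell cycle lists the difference lay with library 2. In libraries 1 and 4 S phase was at -0.10 and -0.08, against a sh-Gpc4 mean of -0.10. G2 and M phases were at -0.07 and -0.08 there, below the sh-Gpc4 mean of -0.06, and kept their direction in 8 of the 9 fits with a library left out. With the microglia list as a covariate the adjusted p was 0.262 for G2 and M phases and 0.0336 for S phase and for radial glia. All 22 dissociation stress genes were negative (median -0.28, 0.000261; 0.657 with an estimated correlation), among them Ier2 (118 ± 33.5 and 161 ± 38.8 CPM). The libraries overlapped in the mean of the dissociation stress list. It was 0.29 in sh-Gpc4 library 1, above sh-Gpc2 libraries 2 (0.05) and 4 (0.20). In sh-Gpc4 libraries 3 and 4 it was -0.24 and -0.29, and in sh-Gpc2 library 1 it was 0.50. Fos, Egr1, Ier2 and Ier3 are also in the FGF/ERK list. Oligodendrocyte precursor genes were negative for 5 of 7 (median -0.72, 0.00101; 0.657 with an estimated correlation), and Olig2 (-2.06, SE 0.53; 0.0232) and Pdgfra (-1.01, SE 0.30; 0.0265) passed in edgeR over the list alone. This list's adjusted p was 0.179 without the 2 libraries that lie apart, sh-Gpc4 library 3 being the lowest.

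The remaining lists that passed between the knockdowns were lower in sh-Gpc4 except for microglia. FGF/ERK targets were negative for 19 of 22 (median -0.28, camera adjusted p = 0.000603, 0.657 with an estimated correlation), with Phlda1 at -0.50 (SE 0.20). The p53 targets were negative for 18 of 22 (median -0.25, 0.00607, 0.657 with an estimated correlation), with Phlda3 at -0.85 (SE 0.32). Notch pathway genes were negative for 18 of 23 (median -0.24, 0.00925, 0.718 with an estimated correlation), with Jag1 at -0.36 (SE 0.13). Hedgehog pathway genes were negative for 11 of 12 (median -0.39, 0.0121, 0.718 with an estimated correlation), with Ptch1 at -0.38 (SE 0.17). Heparan sulfate core proteins, the targets Gpc4 and Gpc2 among them, were negative for 13 of 14 (median -0.25, 0.0135, 0.718 with an estimated correlation), with Sdc4 at -0.69 (SE 0.31). Wnt/beta-catenin targets were negative for 14 of 19 (median -0.19, 0.0441, 0.718 with an estimated correlation), with Bambi at -0.42 (SE 0.13). Microglial genes were positive for 17 of 20 (median 0.20, 0.0113, 0.718 with an estimated correlation), with P2ry12 at 0.89 (SE 0.65). Their mean was low in sh-Gpc2 library 2 (-1.20), while sh-Gpc2 libraries 1 and 4 (0.33 and 0.49) lay above sh-Gpc4 libraries 1 and 3 (0.06 and 0.17). In sh-Gpc2 library 4 the means of FGF/ERK targets (-0.20), Notch (-0.51), Hedgehog (-0.36) and heparan sulfate core proteins (-0.47) lay below sh-Gpc4 libraries 1 and 4. For these lists only sh-Gpc4 library 3 (-0.47, -0.66, -0.59 and -0.57) lay below every sh-Gpc2 library. With the GC trend removed the Notch (0.0681) and Wnt (0.0987) calls ended. With the microglia list as a covariate the adjusted p was 0.175 for Notch, Wnt, Hedgehog and heparan sulfate core proteins. The p53 call ended without the 2 libraries that lie apart (0.123), and Wnt passed in 3 of the 9 fits with a library left out. In all 12 of 28 lists passed, 1 higher and 11 lower, and none with an estimated correlation. Without sh-Gpc2 library 2 the number was 4, all lower, and without sh-Gpc4 library 3 it was 7.

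Among single genes, Plppr1 (a neuronal membrane protein; 79.7 ± 6.51 CPM in sh-Gpc4 and 59.0 ± 1.87 CPM in sh-Gpc2, log2 fold change 0.43, SE 0.10) and Slc15a2 (50.2 ± 2.93 and 34.9 ± 0.189 CPM, 0.53, SE 0.13) had the smallest p of the higher genes, followed by Fbll1 (1.03, SE 0.26), Fam151b (0.92, SE 0.25), Smim17 (0.74, SE 0.21), Cdh13 (0.56, SE 0.16) and 1 ID without a symbol. The lower genes were Grm7 (a glutamate receptor; -0.74, SE 0.17), Cdh1 (-1.54, SE 0.37), Car2 (-0.91, SE 0.23), Slc7a11 (the cystine transporter; 2.23 ± 0.350 and 10.9 ± 9.03 CPM, -2.28, SE 0.58), Olig2, Tgtp2 (an interferon-induced GTPase; -2.49, SE 0.68) and 2 IDs without a symbol. Of 27773 genes 0 passed in edgeR (smallest adjusted p 0.966), 0 in DESeq2 and 0 in limma voom. At an unadjusted p under 0.05 edgeR had 804 genes, 303 higher and 501 lower. Groups did not overlap for 1527 genes, 5.5% against the 10% of chance. Cdh13, Olig2 and Tgtp2 were added after the values were seen.

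Across the 27773 genes the log2 fold changes of the 2 knockdowns against sh-NT correlated with a Pearson r of 0.639, and 76.5% of genes had the same sign. Zkscan1, Plagl2, Frs2, Slc16a11 and Flrt2 had negative values and Siah2 a positive one in both. Both comparisons use the same 3 sh-NT libraries, and in 20 simulations of unchanged groups against these controls r averaged 0.497 (0.481 to 0.507). The observed covariance was 0.0797 and the simulated one 0.0515, a difference of 0.0282. At an unadjusted p under 0.05, 198 genes were higher in both, where independent lists give 16, and 103 were lower in both, where independent lists give 15.8. The counts for independent lists ignore the shared controls, and no overlap was taken from the simulations. The 3 controls were not split, so part of this excess may come from them. Libraries of different groups also varied together, sh-Gpc4 library 3 and sh-Gpc2 library 4 with a residual correlation of 0.831. Neither the correlation nor the overlap tells an effect shared by the hairpins from such variation. Without sh-Gpc2 library 4 the correlation was 0.282, below the 0.481 to 0.507 simulated for the full groups. Genes are not independent replicates.

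The libraries of a group were not alike in the expression of GC-rich genes. On the first principal component of 11968 genes (71.6% of the variance), the sh-NT libraries had scores of -17.6, -25.8 and -13.1. The sh-Gpc4 libraries 1, 3 and 4 had scores of -5.71, 46.7 and 15.8 and the sh-Gpc2 libraries 1, 2 and 4 scores of -17.7, -19.1 and 36.6. Among 10321 protein-coding genes, those with a transcript GC content above 55.1% had a median deviation from their mean of -0.41 log2 units in sh-Gpc4 library 3, -0.29 in sh-Gpc2 library 4 and -0.08 in sh-Gpc4 library 4. It was between 0.08 and 0.17 in the other libraries. The second component (12%) set sh-Gpc2 library 2 (-24.8) apart. With sh-Gpc4 library 3 and sh-Gpc2 library 4 left out, a choice made after seeing the data, the counts of genes remained 0 in all 3 comparisons, and 12, 8 and 10 lists passed. These were not all the same lists: 26 of the 32 calls were kept. In sh-Gpc2 the Notch, heparan sulfate core protein and intermediate progenitor calls were lost and radial glia, S phase and newborn neuron lists were gained, giving 5 higher and 3 lower. Xist, expressed from the inactive X of females, was at 83.6 to 244 CPM and the Y-linked Ddx3y at 37.8 to 94.5 CPM, so each library held RNA of both sexes.

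**Figure D3:**
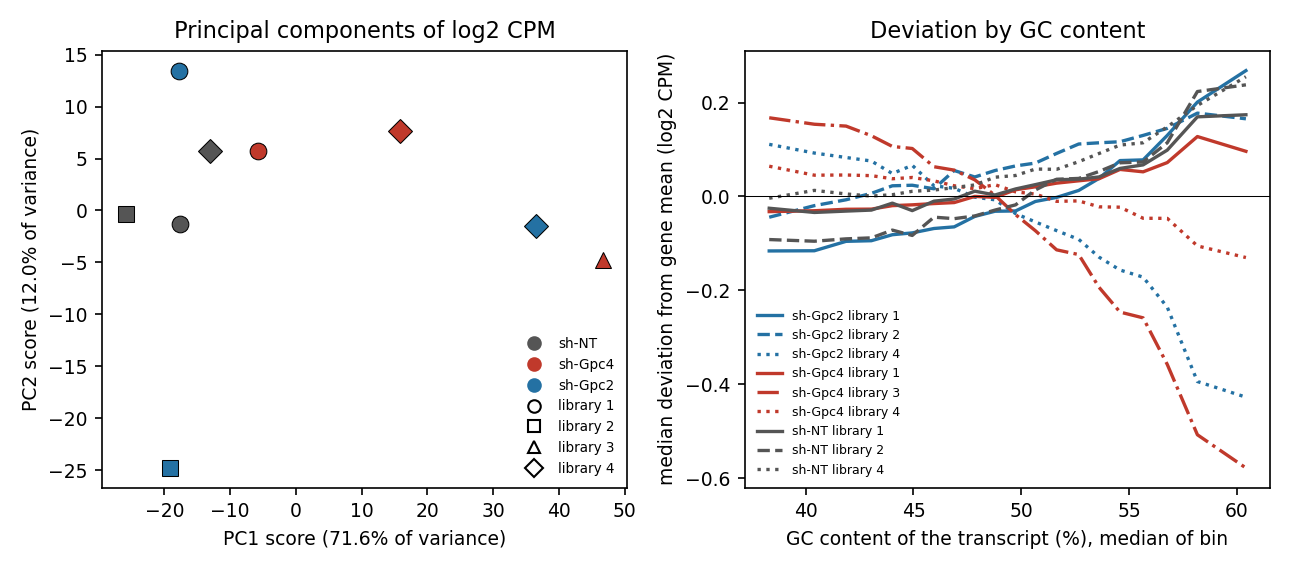
Left, scores of each library on the first and second principal components of log2 CPM (colour, group; marker, library number). Right, median deviation of protein-coding genes from their mean over the 9 libraries (log2 CPM), in 20 bins of transcript GC content (%); sh-Gpc4 library 3 and sh-Gpc2 library 4 fall with rising GC content.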

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

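Groups of 3 libraries are too small for a test of single outlying libraries, so only differences between the effects of the knockdowns were looked for, by the direct contrast of sh-Gpc4 with sh-Gpc2. Camera with an estimated correlation was planned; the other tests in this part that weigh an explanation were chosen after the result was seen.

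Across the lists that passed camera in that contrast, the mean log2 difference (sh-Gpc4 minus sh-Gpc2) was -0.20 for S phase, -0.15 for G2 and M phases and -0.20 for radial glia. It was -0.32 for dissociation stress, -0.79 for oligodendrocyte precursors, -0.30 for FGF/ERK targets, -0.30 for p53 targets and -0.30 for the Notch pathway. For the Hedgehog pathway it was -0.30, for heparan sulfate core proteins -0.29, for Wnt/beta-catenin targets -0.16 and for microglia and macrophages 0.23. None of these lists passed with an estimated correlation (adjusted p of 0.657 to 0.718).

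List calls were found in all 3 comparisons, 32 in total, without a single gene call in edgeR when adjusted over all tested genes. A candidate explanation is that members of a list vary together from library to library more than camera's preset of 0.01 allows. The correlation between members within groups, estimated per list, had a median of 0.218 over the 28 lists, and no call was left when it was used, which is what this explanation needs. The loss of calls does not tell this explanation from a real shift in any of the 3 comparisons. The step with an estimated correlation missed a shift put into simulated counts for sh-Gpc4 against sh-NT (camera adjusted p 0.0892). It recovered the simulated shift for sh-Gpc2 against sh-NT (0.00125) and between the knockdowns (0.00278). Each outcome rests on a single simulation, so they do not set the comparisons apart. Simulated genes also vary independently, unlike the members of these lists, so the recoveries do not decide the question either. After the GC trend was removed 23 of the 32 calls were left, so these passed camera's preset without it. Splits of the libraries other than the groups also gave list calls with this preset. The number left therefore does not decide whether GC content bias caused the calls. Splits of the 6 libraries of each comparison gave up to 14, 13 and 12 lists, against 12, 8 and 12 for the groups (2, 7 and 2 of the 10 splits were as large, the groups included), and 10 splits are too few for a share under 0.05. A shift by the hairpins shared by the members of a list stays open and was not tested apart from this.

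Libraries of the same group lay far apart on the first principal component, sh-Gpc4 library 3 and sh-Gpc2 library 4 at one end. Once the GC trend was removed, 77.4% of the squared deviations between libraries were left (bootstrap SD over genes 0.616). After the microglia list mean was regressed out 70.9% were left, where 1 random covariate leaves 87.5%. These shares argue against GC content bias alone or microglial RNA alone as the source of all deviations between libraries. They cover all deviations, not only those along the first component, so they cannot decide whether either set the positions on it. The assigned group held 38.1% of the squared deviations on this component (exact permutation p = 0.232 over 280 groupings; 26.6% to 64.3% with a library left out), which leaves open whether the knockdowns contribute. RNA quality and cDNA amplification of low-input samples stay open too, as neither is recorded in the labels used here.

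Gpc2 transcripts averaged lower in sh-Gpc4 as well as in sh-Gpc2, although neither passed the threshold. With the GC trend removed, the log2 fold change of Gpc2 in sh-Gpc4 was -0.61 (SE 0.25), and without the 2 libraries that lie apart it was -0.53 (SE 0.21). Both values are more than 2 SE below 0. For GC content bias this argues against it as the whole cause in sh-Gpc4. For the 2 libraries it decides nothing, because the difference that remains without them rests on sh-Gpc4 library 4 (96.6 CPM). The 2 libraries therefore stay open as the cause in sh-Gpc4. In sh-Gpc2 the value was -0.47 (SE 0.25) with the GC trend removed and -0.29 (SE 0.21) without the 2 libraries. Both are within 2 SE of 0, so there both explanations stay open. The lower values lie in sh-Gpc4 libraries 3 and 4, while library 1, at 168 CPM, lies within the sh-NT range. Which cells express Gpc2 was not tested. If Gpc2 were expressed mainly in radial glia and dividing cells, a lower share of these alone would lower their markers about as much. The 125 radial glia, S phase and G2/M genes had a median of only -0.0639 (quartiles -0.182 and 0.0326) against -0.76 for Gpc2, but the 95% interval of Gpc2 (-1.51 to -0.0146) is too wide to exclude it. A response of Gpc2 to the Gpc4 hairpin stays open and was not tested.

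For the counts of genes, all 10 splits of each comparison gave at least the 0 of the groups, which a count of 0 fixes beforehand, so this says nothing about chance. The highest other split gave 0 genes for sh-Gpc4 against sh-NT and for sh-Gpc2 against sh-NT, and 3649 for sh-Gpc4 against sh-Gpc2. That last split set sh-Gpc2 libraries 1 and 2 with sh-Gpc4 library 1 against the rest, which points to a structure of the libraries that the groups do not follow. At an unadjusted p under 0.05 the groups gave 2657, 712 and 804 genes in edgeR and the highest other splits 2191, 3115 and 7933; 10 splits are too few for a share under 0.05.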

How the results depend on the processing

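The GC trend removal, the microglia covariate, the replicate block and leaving out 2 libraries together were chosen after seeing the data. The number of genes changed was 0 under each of 19 alternatives for sh-Gpc2 against sh-NT and for sh-Gpc4 against sh-Gpc2. For sh-Gpc4 against sh-NT it was 0 under 18 and 45 with the DESeq2 Wald test (13 higher, 32 lower). The cause was not tested. Among the 18 the smallest adjusted p was 0.0531, in limma voom, where 9011 genes had an unadjusted p under 0.05. Counts stayed at 0 with any library left out. Fitted to only the 2 groups compared, sh-Gpc4 against sh-NT had 4716 genes at an unadjusted p under 0.05 in edgeR (smallest adjusted p 0.111). In that fit Gpc4 had an edgeR p of 0.00280 (adjusted 0.204). Gpc4 in sh-Gpc4 ranged from -0.62 to -0.39 with a library left out and Gpc2 in sh-Gpc2 from -0.75 to -0.28, and neither passed anywhere. Gpc4 in sh-Gpc2 ranged from -0.434 to 0.0390 with a library left out, positive without sh-Gpc2 library 4, and was 0.0221 without the 2 libraries apart.

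Lists passing camera fell to 0 in all 3 comparisons with an estimated correlation and with fry. For sh-Gpc4 against sh-NT 5 passed with genes above 5 CPM, where fewer genes are tested, and 7 to 12 with a library left out, the lowest without sh-NT library 1. For sh-Gpc2 against sh-NT it was 8 to 10 with a library left out. For sh-Gpc4 against sh-Gpc2 6 passed with the microglia covariate and 4 to 13 with a library left out, the lowest without sh-Gpc2 library 2, and 7 without sh-Gpc4 library 3; the cause was not tested. The correlation between the knockdowns was 0.282 to 0.718 with a library left out, and 0.298 without the 2 libraries apart.

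The titles' replicate numbers could not be tied to columns, so a replicate block was fitted on the columns' own numbers. It gave 0 genes in all 3 comparisons and 8, 8 and 7 lists, not all the same ones. In sh-Gpc4 against sh-NT the Notch, intermediate progenitor, S phase, Hedgehog, FGF/ERK and microglia calls ended (camera adjusted p 0.0885 to 0.205). Newborn neurons (0.0207) and meningeal fibroblasts (0.0345) passed instead. Between the knockdowns the S phase, G2 and M phase, dissociation stress and oligodendrocyte precursor calls stayed, and the others ended (0.0864 to 0.987). Interferon response, GABAergic and meningeal lists passed there instead. Gpc4 in sh-Gpc4 was then at -0.26 and Gpc2 in sh-Gpc2 at -0.60, and the correlation was 0.602. Of the 7 same-number pairs 4 had a residual correlation over 0.1 (range -0.10 to 0.68, against -0.87 to 0.83 for the other pairs). These ranges overlap and do not decide whether the numbers pair libraries. The main fit has no block because no label says what the numbers mark.

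Of 180 gene results checked, 3 changed sign under an alternative. Besides Gpc4 in sh-Gpc2, Dlx6os1 sh-Gpc4 against sh-NT ranged from -3.71 to 0.1004, positive without sh-NT library 1. Between the knockdowns Ly86 ranged from -0.0516 to 0.993, negative without sh-Gpc2 library 2.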

Other observations

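Other cell types were measurable in the sort. Erythroid transcripts such as Hba-x lay between 24.5 and 90.1 CPM over the 9 libraries, endothelial Slc2a1, which other cells also express, between 47.4 and 99.6 CPM, and microglial Apoe, which glia also express, between 287 and 1302 CPM and Ctss between 101 and 480 CPM. The microglia list mean was lowest in sh-Gpc2 library 2, which also had the highest mean of S phase (0.42 log2 units above the overall mean), G2 and M phase (0.38) and radial glia genes (0.35). Interneuron and ventral progenitor markers such as Sp8 (10.2 to 15.1 CPM) were present throughout.

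Several lists passed in no comparison. Camera adjusted p in sh-Gpc4 against sh-NT, sh-Gpc2 against sh-NT and between the knockdowns was 0.536, 0.982 and 0.405 for heparan sulfate synthesis and modification genes, and 0.183, 0.302 and 0.566 for glypican synaptic partners and synapse organizers. It was 0.770, 0.545 and 0.258 for BMP/TGF-beta targets, 0.215, 0.284 and 0.728 for endothelial cells, and 0.402, 0.141 and 0.758 for erythroid cells. For meningeal fibroblasts it was 0.906, 0.938 and 0.994, for Cajal-Retzius cells 0.994, 0.766 and 0.758, and for hippocampal and medial cortical cells 0.770, 0.766 and 0.405. For newborn and migrating neurons it was 0.759, 0.0671 and 0.258, for upper-layer neurons 0.940, 0.257 and 0.299, and for deep-layer neurons 0.874, 0.552 and 0.405. Lists that passed in only part of the comparisons had, elsewhere, 0.127 (sh-Gpc4) and 0.956 (sh-Gpc2) for Wnt/beta-catenin targets, 0.0801 and 0.936 for p53 targets, and 0.0801 and 0.291 for radial glia against sh-NT. Against sh-NT, S phase genes had 0.0885, Hedgehog 0.498, FGF/ERK targets 0.766, GABAergic interneurons 0.214 and oligodendrocyte precursors 0.956 in sh-Gpc2, and dissociation stress had 0.272 in sh-Gpc4. Between the knockdowns it was 0.421 for intermediate progenitors, 0.651 for axon guidance, 0.758 for interferon response, 0.235 for GABAergic interneurons and 0.994 for mural cells.

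Median, mean and test direction differed in sign for some lists, none of which passed. In sh-Gpc4 against sh-NT these were upper-layer neurons (median 0.0105, mean -0.00484, test down), G2 and M phases (0.00632, -0.0414, down), BMP/TGF-beta targets (0.0953, -0.0699, down), meningeal fibroblasts (0.0409, 0.278, down) and hippocampal cells (0.0850, -0.159, up), besides deep-layer neurons. In sh-Gpc2 against sh-NT they were heparan sulfate synthesis (-0.0247, 0.0246, down), Wnt/beta-catenin targets (-0.0110, 0.0256, down), FGF/ERK targets (-0.0153, 0.0304, up), p53 targets (-0.0203, 0.0550, up), meningeal fibroblasts (0.0420, 0.0711, down) and hippocampal cells (-0.00426, 0.0854, down). Between the knockdowns they were deep-layer neurons (0.127, -0.0229, up), erythroid cells (-0.0805, 0.00766, down), meningeal fibroblasts (0.0404, 0.207, down), Cajal-Retzius cells (-0.0523, 0.0902, down) and hippocampal cells (0.0495, -0.245, up).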
